A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

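Total RNA from 6 yeast cultures was labelled with biotin and hybridised to 1-colour Affymetrix arrays, 1 array for each culture, per the labels' protocols. The submitters' processing notes name GCRMA, a method that corrects background by probe sequence, normalises between arrays and summarises the probes of each probe set, with no version. The deposited table holds 1 value for each of 5716 probe sets and 6 arrays. Its values, as deposited by the authors, are taken as log2: they run from 2.49 to at least 14.51 on each array, as GCRMA summaries on that scale do, and neither the labels nor the table states the log base. Signal at the scanner was not analysed here, so background and saturation can be judged from the summaries alone.

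Probe sets were named through a table of the platform's annotation, whose gene symbols were updated by gene identifier to those of the R64 reference gene table. Of the 5716 probe sets, 5498 had 1 gene, 0 had several and 218 had none. All 5498 gene identifiers matched. The 5449 genes were reduced to 5350 by keeping probe sets with a log2 value of at least 4 on at least 3 of the 6 arrays, whatever their group. Where several probe sets stood for a gene, as for 47 genes, the one with the highest mean over all arrays was used. Of the tested probe sets 107 carry a suffix that marks probes shared with other sequences, so their genes can share signal with close relatives. The 212 unnamed probe sets that passed the filter were tested apart.

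Groups were taken from the sample titles. PI3K was compared with KD by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group means without a block), with Benjamini-Hochberg adjustment over the 5350 genes and a threshold of 0.05. Residual degrees of freedom were 4 and the prior added 2.97; the median gene had a residual SD of 0.20. Of 33 gene lists fixed before the data were examined, 32 had at least 3 tested members; the other, marker genes of the strain, had 2. Of 735 symbols in the lists 734 were matched to a gene. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 32 lists. A list is called shifted where camera with the preset correlation gave an adjusted p under 0.05. The comparison, the lists and the rule for named genes were fixed before the data were examined. That rule takes the 12 largest log2 fold changes each way among called genes with the groups apart, or all where fewer pass. It adds, by smallest p, up to 4 members of a shifted list in its direction and 2 against it, up to 2 called members of each other list, and SLT2, RLM1, GAL1, GAL7, GAL10, MSS4 and the marker genes whatever their values. Not all genes it takes are named in the text. PIR3, PIR1 and CIS3 in the account of the cell wall integrity list, and the genes of the closing observations, fall outside it.

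Both groups carry replicate numbers 1 to 3. Whether these numbers pair the samples was checked on the residuals, and they were not taken to do so. Other settings, also fixed by then, were no filter, a stricter filter at a log2 value of 6, median-centring, quantile normalisation, eBayes with a trend and robust variances, array weights, a replicate block, the mean of a gene's probe sets, treat against a fold change of 1.2 and leaving out each array. Settings chosen after the data were examined were the array side as a covariate and the removal of a length trend. That trend was fitted by loess with a span of 0.5 on the logarithm of the gene length in the reference gene table. Of these lengths 97.0% were multiples of 3, so they are not the coding length for every gene. A side found from the same values as the test reduces the residual spread by selection, so p-values from that covariate are too small by an unknown amount.

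The limma test was run on simulated data of 5393 probe sets, 200 of them changed, for the comparison of PI3K with KD. The simulated spread was the one left on these arrays after the array side was fitted, drawn independently for each probe set. Without a second factor the simulated data thus varied less than these arrays. There the test recovered 100% of changes of log2 size 1 and of size 2, with 11 false calls. With a simulated second factor shared between the groups as the array sides are, it recovered 78% at size 1 and 99% at size 2, with 1 false call, and with that factor as a covariate 98% and 100%, with 5 false calls. Where the covariate was fitted without a simulated second factor, it recovered 100% at each size, with 15 false calls. The covariate was the known factor and was not found from the simulated values. These counts therefore do not show how many false calls a side found from the tested values gives. Probe sets of another species, which some yeast arrays carry, were not analysed here, and a check of GC content needs a genome and was not run. The transgene was not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.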

Results

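Gene expression was measured in budding yeast, Saccharomyces cerevisiae strain BY4741, carrying a galactose-inducible copy of p110α-CAAX. This protein is the catalytic subunit of a mammalian phosphoinositide 3-kinase, the product of PIK3CA, joined to a motif that directs proteins to membranes. Its substrate at the plasma membrane is the phosphoinositide that Mss4 makes in yeast. Cells with the active form (PI3K) were set against cells with the kinase-dead substitution K802R (KD). Cultures were grown in raffinose medium, given 2% galactose for 4 h and profiled on Affymetrix arrays, with 3 biological replicates in each group and 1 array for each.

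The 6 arrays held 5716 probe sets as log2 values, the lowest at 2.49 and the highest of each array at 14.51 or more, with array medians between 9.49 and 9.54. Pearson correlations between pairs of arrays ranged from 0.965 to 0.995 over the 5350 genes tested, and the number of arrays limits the precision of each value. The arrays also varied in a way that the groups did not account for. After each group's mean was removed from every gene, the first principal component held 70.4% of the remaining variance. It placed PI3K 1, PI3K 3 and KD 3 on one side (side A) and PI3K 2, KD 1 and KD 2 on the other (side B). With the group means left in, the first component held 51.2% of the variance and parted the same sides. PI3K and KD parted only on the second, with 30.0%. KD 3 correlated more with PI3K 1 (0.983) than with KD 1 (0.968) or KD 2 (0.973). PI3K 2 correlated more with KD 1 (0.988) than with PI3K 1 (0.984) or PI3K 3 (0.978). The labels name no batch, and the sides were found from the values, so the difference between PI3K and KD is also given within each side for each list that shifted. Side A holds 1 KD array and side B 1 PI3K array, so each difference within a side rests on an unreplicated array.

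The comparison of PI3K with KD asks which transcripts respond to the kinase activity of p110α-CAAX rather than to its production. Several of the genes that were higher with the active kinase belong to the yeast response to cell wall stress. PRM5, a membrane protein gene widely used as a reporter of that response, rose from a log2 value of 8.36 ± 0.10 (SD, n = 3) in KD to 11.05 ± 0.29 in PI3K. This was a 6.45-fold difference, with a log2 fold change of 2.69 (SE 0.17, limma adjusted p = 0.00447). CRG1, which encodes a methyltransferase for the drug cantharidin, rose 5.99-fold (log2 fold change 2.58, SE 0.21, adjusted p = 0.0141). SLT2, the MAP kinase of the cell wall integrity pathway, rose 2.95-fold from 9.99 ± 0.05 to 11.55 ± 0.35 (log2 fold change 1.56, SE 0.18, adjusted p = 0.0392).

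In all, 13 of the 5350 genes passed an adjusted p of 0.05 in limma, 12 of them higher and 1 lower in PI3K, and 11 had changed at least 2-fold. Besides the genes above, those that rose were SRL3 (log2 fold change 2.26), the glycerol transporter gene STL1 (2.18), PRM10 (1.75), RTC3 (1.37) and RTS3 (1.33). The others were GSC2, an alternative catalytic subunit of glucan synthase (1.18), ARO10, a decarboxylase of amino acid breakdown (1.01), ECL1 (0.96) and CWP1, a cell wall mannoprotein (0.91). Their adjusted p-values lay between 0.0372 and 0.0485. WSC4, a relative of the cell wall stress sensors, was the gene that fell, from 8.05 ± 0.13 to 6.87 ± 0.15 (log2 fold change -1.18, SE 0.13, adjusted p = 0.0392). The 3 PI3K values lay apart from the 3 KD values for each of the 13 genes. This held for 1109 of the 5350 genes, or 20.7%, where 10% is the share that chance gives. At an unadjusted p under 0.05, 425 genes were higher and 352 lower. That balance depended on the setting: more genes were lower with quantile normalisation (380 higher and 448 lower), with a trend of gene length removed, a setting chosen after the data were examined (403 and 454), with array weights (1463 and 1677) and without KD 3 (598 and 698). The count of called genes moved with single arrays: 2 genes passed without PI3K 1, 1 without PI3K 2, 2 without PI3K 3, 1 without KD 1, 6 without KD 3 and 0 without KD 2, where 476 had an unadjusted p under 0.05. SLT2, GSC2, CWP1, RTC3, RTS3, ARO10, ECL1 and WSC4 passed in none of these 6 fits. With the array side as a covariate, a setting chosen after the data were examined, 185 genes passed, 142 higher and 43 lower, and these included all 13.

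The cell wall integrity list, targets and components of the Slt2 and Rlm1 pathway, was higher in PI3K as a group. Each of its 25 tested genes had a positive difference, with a median log2 fold change of 0.65. PRM5, CRG1, SRL3, SLT2, GSC2 and CWP1 rose over all genes tested, and 19 rose when adjusted over the list alone. Among the members that did not pass over all genes, PIR3, a cell wall protein, had a log2 fold change of 2.58 (SE 0.43, adjusted p = 0.112). RLM1, the transcription factor of the pathway, had one of 0.65 (SE 0.13, adjusted p = 0.129). The cell wall protein genes PIR1 (0.46, SE 0.45) and CIS3 (0.14, SE 0.10) had smaller differences. PIR3, PIR1 and CIS3 were chosen after their values were seen. The list passed the camera test (adjusted p = 7.82e-21 over 32 lists) but not with a correlation estimated from the arrays (adjusted p = 0.131 with an estimated correlation), while fry, which asks only whether the list's genes move one way, gave an adjusted p of 0.0183. The list's median difference was 0.74 within side A and 0.56 within side B, and 24 and 25 of the 25 genes were higher in PI3K there.

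**Figure D1:**
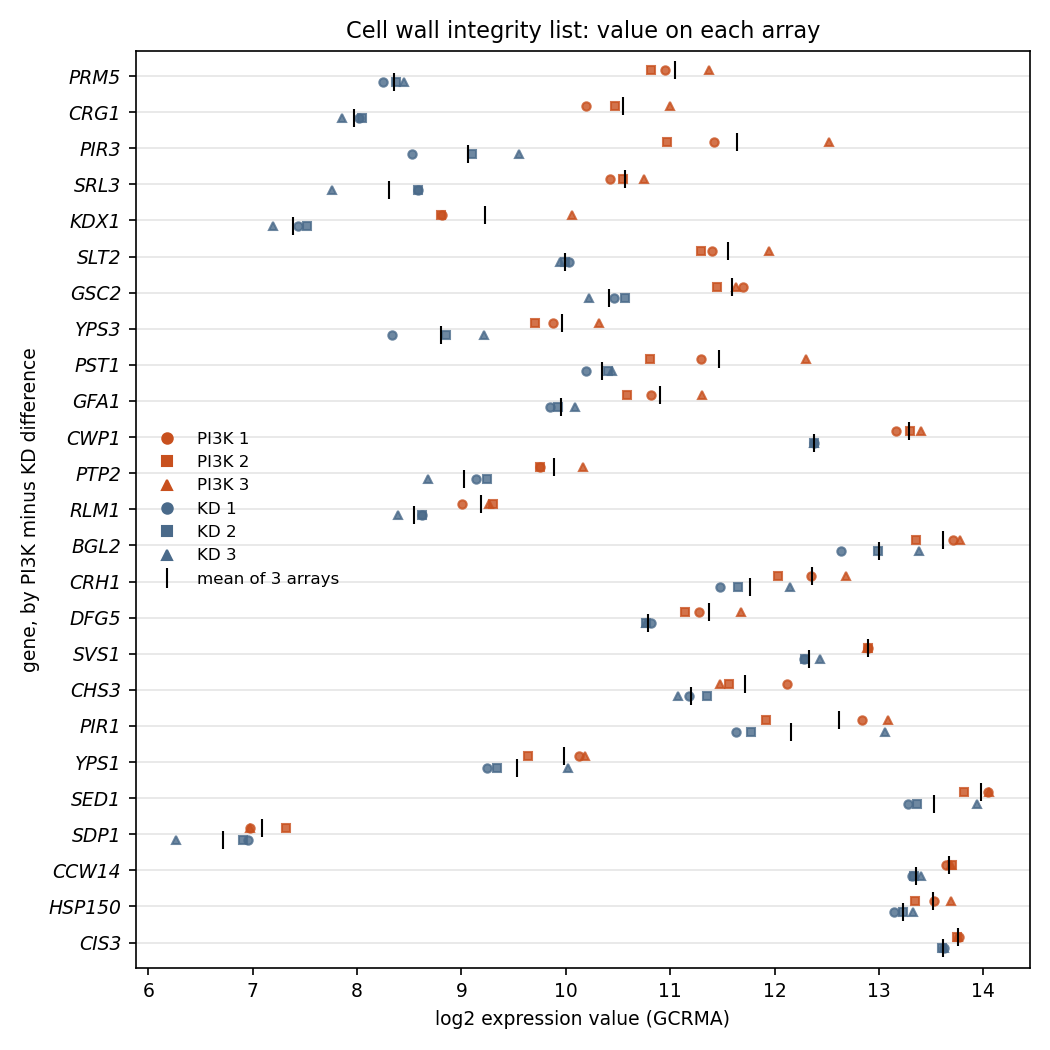
The log2 value of each of the 25 genes of the cell wall integrity list, one line per gene, on each of the 6 arrays, with PI3K arrays in orange and KD arrays in blue and a bar at each mean of 3 arrays. The PI3K mean lies to the right of the KD mean for each gene, from a difference of 2.69 for PRM5 down to 0.14 for CIS3.

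Genes of other stress programs were also higher, by less. The general stress list, driven by Msn2 and Msn4, had a median log2 fold change of 0.38 over 32 genes, 29 of them higher, but no member passed over all genes and 5 rose when adjusted over the list alone. Its smallest p-values belonged to SDS24 (0.95), the chaperone gene HSP42 (1.41, adjusted p = 0.0998), the transaldolase gene NQM1 (1.67, adjusted p = 0.112) and the trehalose phosphatase gene TPS2 (0.86). GPH1, glycogen phosphorylase, went the other way at -0.20. This list leaned on 1 array: its median relative to the KD means was 0.82 on PI3K 3, 0.18 on PI3K 1 and 0.12 on PI3K 2, and its median log2 fold change was 0.20 without PI3K 3. Within side A it was 0.60 and within side B 0.11.

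In the osmotic stress list, genes induced through the Hog1 kinase, STL1 and RTC3 rose, 5 of 17 rose when adjusted over the list alone and the median was 0.28. The glycerol synthesis genes GPD1 (0.99) and GPP2 (0.64) did not pass over all genes, and the transcription factor gene HOT1 had a difference of -0.21. Without PI3K 3 the list's median was 0.06, and it was 0.48 within side A and 0.09 within side B. The heat shock list had a median of 0.22, with HSP42 at its head, CUR1 at 1.00, HSP78 at 0.62 and HSC82 at -0.05, and the median was 0.23 within side A and 0.07 within side B. No member of its 24 passed over all genes and 1 rose when adjusted over the list alone. The osmotic stress and heat shock lists each share members with the general stress list, HSP42 among them for heat shock, so their shifts are not independent. These 3 lists passed camera (adjusted p = 2.10e-07 for general stress, 0.000600 for osmotic stress and 0.000472 for heat shock). None passed with a correlation estimated from the arrays: adjusted p = 0.427 with an estimated correlation for general stress, adjusted p = 0.242 with an estimated correlation for osmotic stress and adjusted p = 0.321 with an estimated correlation for heat shock. None passed fry either (adjusted p = 0.195, 0.0530 and 0.0811 in the same order). The osmotic stress call also ended with array weights (median 0.15).

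Ribosome assembly factors were lower in PI3K. Of 37 genes of the ribosome biogenesis list, 34 were lower, and the median log2 fold change was -0.32. The differences were small and none passed, over all genes or when adjusted over the list alone. The smallest p-values belonged to NOC3 (-0.47), RIX1 (-0.45), ERB1 (-0.46) and UTP10 (-0.49), and the box C/D snoRNP gene NOP1 was at 0.17. The list passed camera (adjusted p = 1.60e-08; adjusted p = 0.131 with an estimated correlation) and fry (adjusted p = 0.0229), and its median was -0.27 within side A and -0.34 within side B. The ribosomal protein list did not shift with it: its 29 genes had a median of 0.00 and an adjusted p of 0.779. Those genes had a median level of 14.04, near the highest values of the arrays. With a smooth trend of gene length removed from each array, a setting chosen after the data were examined, their median was -0.11 and the list passed camera.

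Lists of the cell cycle were lower as well. The list of G1/S genes bound by SBF and MBF had a median log2 fold change of -0.22, with 21 of 28 genes lower. MNN1 (-0.38), RNR1 (-0.47), PRI2 (-0.31) and POL1 (-0.39) did not pass, nor did GIC2 (0.45), which went against them. The G2/M list had a median of -0.25, with 17 of 21 genes lower, and WSC4 fell, the one member to do so over all genes or adjusted over the list alone. HOF1 (-0.43), CLB1 (-0.40) and IRC8 (-0.34) did not pass, nor did MOB1 (0.46). WSC4, a relative of the cell wall stress sensors, is not itself part of mitosis. Both lists passed camera (adjusted p = 0.00223 for G1/S and 0.00138 for G2/M; adjusted p = 0.131 with an estimated correlation for each) and fry (adjusted p = 0.0308 and 0.0229). Without KD 3 the G1/S list did not pass (median -0.21), without KD 2 the G2/M median was -0.16, and with array weights neither list passed (medians -0.22 for each). Within sides A and B the medians were -0.15 and -0.24 for G1/S and -0.25 and -0.26 for G2/M.

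Genes of iron uptake were lower, and those of the actin cytoskeleton higher. In the iron list, regulated by Aft1 and Aft2, 17 of 19 genes were lower, with a median of -0.28, and 3 fell and 1 rose when adjusted over the list alone. FIT2 (-1.22), FIT3 (-0.72), which encode cell wall proteins that hold siderophores, and the siderophore transporter gene SIT1 (-0.70) lay against ISU1 (0.77), a scaffold for iron-sulfur clusters, and HMX1 (0.40), a heme oxygenase. None of these passed over all genes. In the list of actin patches and endocytosis 27 of 30 genes were higher, with a median of 0.22. The smallest p-values belonged to CAP1 (0.62), VRP1 (0.55), ARC18 (0.47) and ARP2 (0.69, with overlapping groups), and CRN1 stood at -0.19. No member of it passed, in either adjustment. Within sides A and B the medians were -0.13 and -0.37 for iron and 0.12 and 0.23 for actin. The camera adjusted p was 0.000253 for iron and 5.72e-05 for actin (adjusted p = 0.135 and 0.131 with an estimated correlation), and fry gave an adjusted p of 0.0229 and 0.0183.

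Of the 6 remaining lists that passed camera, the phospholipid synthesis list was lower, with a median of -0.17 and 18 of 20 genes lower, among them ITR1 (-0.42) and INO1 (-1.13, SE 0.53). The calcineurin list had a median of 0.10. GSC2, which also belongs to the cell wall integrity list, rose over all genes, and 2 of 14 rose when adjusted over the list alone, while PUN1 stood at 0.97 and PHO89 at -0.43. The proteasome list had a median of 0.17, with 30 of 34 genes higher and PRE10 (0.33) first by p. The list of autophagy and vacuolar proteases had a median of 0.17. ATG8, which encodes the ubiquitin-like protein of the autophagosome, had the smallest p in it (1.27, adjusted p = 0.126), and 1 of 18 rose when adjusted over the list alone. The respiratory chain list had a median of 0.12, with RIP1 at 1.04, SDH2 at 0.75 and HAP4 at -0.16, and the list of the tricarboxylic acid cycle, glyoxylate cycle and gluconeogenesis 0.16, with IDP2 at 1.30 and ICL1 at -0.26. No other member of these 6 lists passed over all genes, and none of phospholipid, proteasome, respiratory chain or tricarboxylic acid genes did so adjusted over the list alone. Within sides A and B the medians were -0.20 and -0.24 for phospholipid, 0.29 and 0.05 for calcineurin, 0.17 and 0.16 for proteasome and 0.27 and 0.07 for autophagy. They were 0.21 and 0.12 for the respiratory chain and 0.20 and 0.07 for the tricarboxylic acid list. The camera adjusted p-values of the 6 lists lay between 0.00125 and 0.0177. None passed with a correlation estimated from the arrays: adjusted p = 0.187 with an estimated correlation for phospholipid, and in the same test an adjusted p = 0.326 for calcineurin, 0.153 for proteasome, 0.321 for autophagy, 0.474 for the respiratory chain and 0.427 for the tricarboxylic acid list. Only the proteasome list passed fry (adjusted p = 0.0229), and the fry adjusted p was 0.0530 for phospholipid, 0.0683 for calcineurin, 0.127 for autophagy, 0.166 for the respiratory chain and 0.195 for the tricarboxylic acid list. Leaving out KD 3 ended the calls of phospholipid (median -0.15), calcineurin (0.06), autophagy (0.11) and the respiratory chain (0.04). Leaving out PI3K 3 ended those of the tricarboxylic acid (0.10) and autophagy (0.14) lists, PI3K 2 those of phospholipid (-0.15) and the respiratory chain (0.07), and KD 1 that of the tricarboxylic acid list (0.13), while without KD 2 the calcineurin median was 0.18. Array weights ended all of these calls but that of the proteasome list, and the respiratory chain median was then -0.00497, below 0. The proteasome call ended with the length trend removed (0.07), and the array side as a covariate ended that of the tricarboxylic acid list (0.07).

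**Figure D2:**
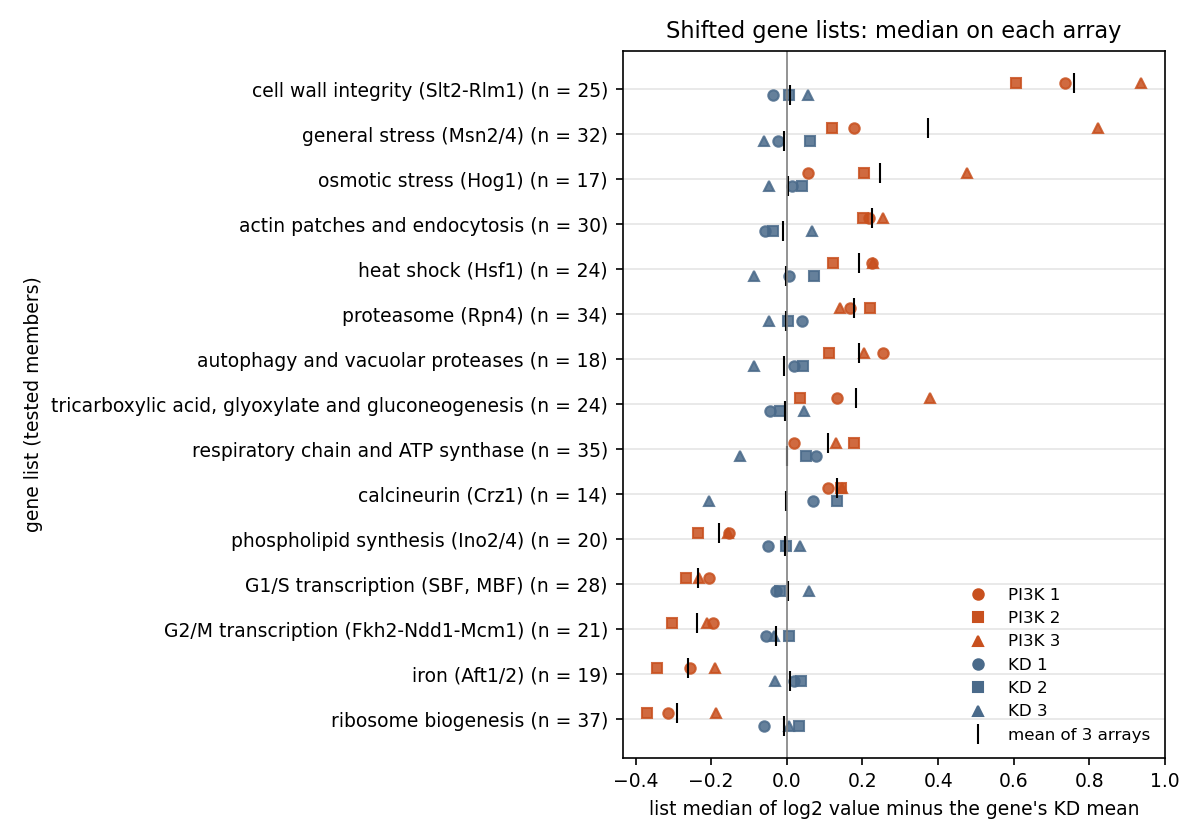
The median, over the tested members of each of the 15 gene lists past the camera test, of the log2 value minus the gene's KD mean, on each array, with PI3K in orange, KD in blue and bars at the mean of 3 arrays. The cell wall integrity medians of PI3K 1, PI3K 2 and PI3K 3 were 0.73, 0.61 and 0.94, and the general stress median was 0.82 on PI3K 3 against 0.18 and 0.12 on the others.

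The genes that report on induction and on the strain showed no called difference between groups. GAL1, GAL7 and GAL10, the galactose enzymes induced from the same kind of promoter as the transgene, had log2 fold changes of -0.02, 0.17 and -0.02 at levels of 13.74 to 14.11, near the top of the range. The galactose regulon list had a median of -0.02 and an adjusted p of 0.854, with a mean below 0 and an upward test direction. The marker genes HIS3 and LEU2 differed by 0.09 and -0.03, and their list was too short to test. The signs of GAL1, GAL10, HIS3, LEU2 and the galactose list's median changed between settings. The pheromone response (median -0.04) and the markers of alpha cells and diploids (0.08), which a haploid of mating type a does not use, did not shift, with adjusted p of 0.405 and 0.174. The alpha-cell and diploid list passed without KD 1 (median 0.13), without KD 2 (0.14) and with the array side as a covariate (0.16), and its median was -0.09 without KD 3, the array on which it was lowest. In camera with an estimated correlation it did not pass, with that covariate (adjusted p = 0.640) or without it (adjusted p = 0.642). MSS4, the kinase gene for the substrate of p110α, had a difference of -0.42 (SE 0.15, adjusted p = 0.274), and the list of phosphoinositide kinases and phosphatases a median of -0.09 (adjusted p = 0.276).

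Further lists that did not pass camera were the unfolded protein response (median 0.07, adjusted p = 0.640), oxidative stress (0.07, 0.608), hexose transport and glycolysis (0.03, 0.783), amino acid biosynthesis (0.01, 0.988) and methionine and sulfur (0.07, 0.285). The amino acid list had a positive median and a downward test direction. The others were phosphate (-0.14, adjusted p = 0.185), ergosterol (0.02, 0.854), sphingolipid and TORC2 (0.07, 0.276), drug resistance (0.10, 0.285), histones (-0.15, 0.0623), daughter-cell separation (-0.06, 0.405) and the DNA damage response (0.12, 0.276). Daughter-cell separation had a mean of 0.05 against its negative median and test. Histones passed without PI3K 2 (median -0.21), and also with quantile normalisation, a variance trend, averaged probe sets or the length trend removed, and their median was -0.04 without PI3K 3. Daughter-cell separation passed with the array side as a covariate (-0.12) and drug resistance with the length trend removed (0.05). No member of the 17 lists that did not pass camera passed over all genes. Adjusted over the list alone, 2 genes rose and 3 fell in the phosphate list, and 1 rose in each of the alpha-cell and diploid, sphingolipid and drug resistance lists.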

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

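The tests of the array sides, of exchanged labels, of an unequal share of the sides and of slower growth, and the counts over other splits of the arrays without a covariate, were chosen after the result was seen.

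Signals in data outside the comparison of named genes came from probe sets that the annotation used here pairs with no gene. Of 212 such probe sets tested apart, 4 were higher in PI3K, with all 3 PI3K values above all 3 KD values. The first had a log2 fold change of 1.50, from 10.81 ± 0.08 (SD, n = 3) in KD to 12.31 ± 0.17 in PI3K (limma adjusted p = 0.00262 over these probe sets). The others had log2 fold changes of 1.12, 1.09 and 0.97, with adjusted p of 0.0109, 0.0122 and 0.0495. No explanation was tested for them.

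The 6 arrays fell on 2 sides, with PI3K 1, PI3K 3 and KD 3 against PI3K 2, KD 1 and KD 2. Each group's mean was removed before the sides were found, so each group had to have arrays on both. That sides found in this way cross the groups is therefore not a finding. The tables argue against a fault of KD 3 alone, since the difference between sides within PI3K and that within KD, which share no array, correlated across genes at r = 0.659, though genes are not independent replicates and the sides were chosen from the data. Exchanged labels of PI3K 2 and KD 3 could not be tested apart from the labels themselves. Over the cell wall integrity list PI3K 2 lay above KD 1 and KD 2 by a median of 0.56 and KD 3 by 0.08. This argues against an exchange only if the list marks the active kinase. That link rests here on the labels, and the transgene was not analysed, so an exchange stays open. Gene length was related to the difference between sides (Spearman rho = 0.154 across genes), so a length-dependent step such as RNA quality or labelling may be part of it. The difference between PI3K and KD had a larger rank correlation with length (rho = -0.294), so the same kind of step may be part of the comparison of groups, and its cause stays open. Neither trend was steady. From the shortest to the longest of 5 length classes its medians were 0.00, -0.01, 0.13, -0.05 and -0.14. Those of side A minus side B ranged more widely, at -0.40, -0.34, 0.01, 0.02 and -0.13, so rho does not rank the 2 trends by size. For the sides, with the length trend removed the correlation between the differences was still 0.599, which argues against length as the whole cause. A shared day of culture or hybridisation, or a physiological difference between cultures, stays open and was not tested.

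The cell wall integrity genes were higher in PI3K. The median differences within sides, 0.74 in A and 0.56 in B, argue against an unequal share of the sides between groups. Side A holds 1 KD array and side B 1 PI3K array, so each difference rests on an unreplicated array. The side B value is the one also given for exchanged labels. A length trend is argued against by the median of 0.71 after its removal. The 6 arrays can be split in 10 ways, too few for a share under 0.05. The real split called 13 genes, 11 of them at least 2-fold, and 2 splits, the real one included, called as many in either count. The highest other split, that into sides A and B, called 754 and 73. Those sides were chosen from these same values for their large spread, so high counts there follow in part from the choice. They are no separate evidence of a structure of the samples. For shifted lists the real split gave 15 and the highest other split, PI3K 1, PI3K 3 and KD 1 against the rest, 15 (2 splits as large, the real one included). Every other split shifted at least 3 lists, so a camera call alone does not set the real grouping apart. With sides found anew in each split as a covariate the real split gave 185 genes, the highest other, again sides A against B, 1329, and 2 splits, the real one included, as many. The kinase activity that the design names stays open as a hypothesis, and so does an unequal amount of the active and the kinase-dead protein, which was not tested.

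Stress genes were higher and ribosome biogenesis genes lower in PI3K, which may be a general response to slower growth. Such a response would lower the ribosomal protein genes by about as much as the assembly factors, and their median log2 fold change was -0.0036. At a median level of 14.04 these transcripts lie near the top of the range, so the test does not decide, and with the length trend removed their median was -0.11. The growth of the cultures was not analysed here.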

How the results depend on the processing

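The array side as a covariate and the removal of a length trend were chosen after the result was seen; the other alternatives were planned.

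The 13 changed genes, 11 of them at least 2-fold, became 2808 and 109 with array weights, whose fit did not converge and gave weights from 0.15 for KD 3 to 5.75 for KD 2, 2 and 2 with treat, and 185 and 31 with the array side as a covariate. Leaving out 1 array gave 0 to 6 genes, and 0 to 6 at least 2-fold, with fewer samples in each fit. With the replicate number as a block the counts were 40 and 31, though the numbers were not taken to pair the samples. The residuals of same-numbered arrays correlated at -0.49, 0.48 and 0.39, and 2 of 6 arrays matched best with their own number. Arrays numbered 2 share a side, as do those numbered 3, while those numbered 1 do not. The check therefore could not show a pairing weaker than the sides. Other settings gave 11 to 15 genes, and the length correction kept 9 of the 13 among its 13. The 15 shifted lists became 0 with an estimated correlation, 7 with fry and 7 with array weights, and 10 to 16 with 1 array left out. The cell wall integrity list kept its direction in every setting, with medians from 0.64 to 0.81 and camera calls in all but the estimated correlation (0.65, adjusted p = 0.131). For these changes the cause was not tested. PRM5 passed in 16 of 17 other settings, CRG1 in 14 and the other 11 genes in 7 to 11. With 1 array left out PRM5 passed in 5 of 6 fits, CRG1 in 3, SRL3, STL1 and PRM10 in 1 each and the other 8, SLT2 among them, in 0. No call was reversed by its test direction, and 52 uncalled values of lists and genes changed theirs. Low values limit little, as the filters at 4 and 6 gave the same counts, whereas values near 14 can hide changes. The planned test of probe sets of another species was not run.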

Other observations

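The genes described here were named after their values were seen, in a fit with the array side as a covariate that was itself chosen after the result was seen; the tests of endosomal traffic and of neighbouring genes were written before their results.

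In that fit 3 of the 37 tested genes of the ribosome biogenesis list were among the 43 lower genes: DBP3 (log2 fold change -0.72), ENP1 (-0.62) and YTM1 (-0.53). Other lower genes were URB2 (-0.59), MTR4 (-0.58), UTP8 (-0.58), PLB2, a phospholipase B (-1.02), the malic enzyme gene MAE1 (-0.88), the formate dehydrogenase gene FDH1 (-0.80), the glycine cleavage gene GCV2 (-0.77) and PSD1, phosphatidylserine decarboxylase of mitochondria (-0.68). Without the covariate the log2 fold changes of these named genes had the same sign and none of them passed, while WSC4, also among the 43, did.

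Among the 142 higher genes were YPK2, a kinase gene of the TORC2 pathway (1.12), the wall mannosyltransferase gene KTR2 (1.23), CHS7, which serves the export of chitin synthase (0.63), and GFA1, the entry enzyme of chitin precursor synthesis (0.84). Others were AFR1 (1.38), RCN2, a regulator of calcineurin (0.78), CMP2, a catalytic subunit of it (0.76), and SDH6 (0.82), SDH8 (0.63) and SDH5 (0.53) of succinate dehydrogenase assembly. STE3, the a-factor receptor gene of alpha cells, was at 0.71 with a level of 7.83 ± 0.26 in PI3K and 6.98 ± 0.25 in KD. None of these named higher genes passed without the covariate.

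Several higher genes serve traffic to endosomes and the vacuole: PEP12 (1.00), GGA1 (0.98), YPT53 (0.86), SNF8 (0.67), NYV1 (0.61), VTI1 (0.59), SEC17 (0.59), DID2 (0.55) and TLG1 (0.48). Without the covariate none of these 9 passed, and DID2 (0.38) and TLG1 (0.32) had overlapping groups. The hypothesis that this machinery is higher as a group was tested on a list of 50 such genes, written after those names were seen. Without the covariate 36 of the 50 were higher (median 0.09, camera p = 0.00335, n = 50 genes), but not apart from other genes with an estimated correlation (p = 0.312, n = 50 genes), and the list holds the 9 genes that prompted it. The 41 others gave a median of 0.07 (camera p = 0.386, n = 41 genes). Leaving out called members pushes the rest toward no shift, so the test does not decide and the hypothesis stays open.

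Some called genes lie side by side in the genome, such as RLM1, YPL088W and YDC1, and a hypothesis was that neighbours changed together more often than chance gives. There were 5 neighbouring pairs called in one direction, against a mean of 3.70 in 10000 random draws of genes (one-sided permutation p = 0.307), which did not bear it out.

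The largest spread within groups belonged to genes that followed the array sides. The sides were found from that same spread, in which such genes weigh most, so this follows in part from the choice. HAC1, which encodes the transcription factor of the unfolded protein response, read 11.93, 9.90 and 12.20 on PI3K 1, PI3K 2 and PI3K 3 and 9.46, 9.79 and 12.27 on KD 1, KD 2 and KD 3. YNL190W read 12.23, 10.39 and 12.43 and then 10.20, 10.21 and 12.97 in the same order, and YOR302W, the upstream reading frame of CPA1, read 9.36, 7.39, 9.56, 7.62, 7.28 and 10.28. HXT11 went the other way, at 5.43 on KD 1 and 2.62 on KD 3, near that array's lowest value of 2.49.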
